A study of Mnemiopsis leidyi with 40 samples.

How the data were processed

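Messenger RNA was measured in 40 single embryos of the ctenophore (comb jelly) Mnemiopsis leidyi, 2 embryos at each of 20 developmental times from 0 to 20 h. Per the labels' protocols, total RNA was extracted from each embryo with a phenol-based reagent after repeated freezing and thawing, and libraries were made by CEL-Seq, which tags the RNA of each sample with a barcode, amplifies it by in vitro transcription and sequences the 3' ends of transcripts. Per the labels' protocols, the barcodes also held a unique molecular identifier. Whether reads that share an identifier were merged before counting is not given in the sources used here, so the counts are treated as reads, and all intervals and floors cover counting error only.

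The authors deposited a table of whole-number counts per gene model and embryo. The submitters' processing notes name CASAVA 1.8, Bowtie2 2.1.0 and HTSeq 0.5.4p3. The genome build and the annotation are not given in the sources used here, nor is the strand setting of the counting. The table holds 16548 gene models, of which 1952 had no read in any embryo, and 5 totals that name no gene. Those totals stayed out of library sizes and tests. Of all reads of an embryo, taken as the sum of the gene models and of the totals for unaligned reads, reads outside gene models and ambiguous reads, a median of 49.16% were not aligned (range 45.08% to 68.71%) and a median of 3.155% were ambiguous between gene models. Reads outside gene models made up a median of 32.95% of aligned reads (range 27.04% to 46.48%), and gene models took a median of 30.82% of all reads. Reads that overlap several gene models, or that fit near-identical copies of a gene, may have been dropped or split by the authors' counting, so values of genes with close copies are uncertain.

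A second deposited table, the authors' sheet of samples, gives for each embryo other values that are not measurements: its developmental time, its barcode, its lanes and the Illumina index number of its library. Each embryo was sequenced in 2 lanes that the count table sums. The index numbers were 6 for every embryo numbered replicate 1 and 12 for every embryo numbered replicate 2, so that the libraries fall into 2 pools of 20 embryos, each with 1 embryo of every time. These are called pool 6 and pool 12 here. The pairing of embryos by pool comes from this sheet. Same-age differences between the pools, compared between 171 pairs of times without 10 h, had a median correlation of 0.10 across genes (range -0.227 to 0.52), and 86 of the 171 correlations were over 0.1. Nothing in the labels says whether same-age embryos came from the same spawning, and p-values measure the spread between these single embryos, which includes the difference between the pools.

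The gene model IDs were looked up in a RefSeq gene table of the organism with 19625 genes (assembly crg_Mlei_v2), and 0 of the 16548 IDs matched. The files do not pair IDs with names, so genes are given by ID and no function is stated. Gene lists for functions and cell types had been set before the data were examined, but with no names none could be built, and their tests (camera and fry, with preset and estimated correlations between genes) were not run. No row of the table was a spike-in RNA, so scaling by spike-ins was not run.

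The windows of time were set before the data were examined: early (0 to 3 h, 8 embryos), middle (4 to 9 h, 22 embryos) and late (10 to 20 h, 10 embryos). The main tests, the named-gene rule and the alternatives were also set then, except the alternatives that the closing section names as added. Counts were analysed with edgeR 4.0.16 in R 4.3.3. Gene models with too few counts were removed by filterByExpr with the 20 times as groups and its default count minimum of 10, which left 9576 genes. Library sizes were scaled by TMM, and a negative binomial model with a 20-level factor for time was fitted to all 40 embryos by quasi-likelihood (median coefficient of biological variation 0.504, prior degrees of freedom 9.63). An F test over all times gave the genes that changed with time. Window comparisons were contrasts between the means of the time coefficients, so that each sampled time has the same weight, and neighbouring times were compared with 19 further contrasts. P-values were adjusted by the Benjamini-Hochberg method, within a contrast for the windows and over all 19 contrasts together for the intervals. A gene was called at an adjusted p below 0.05 and, for contrasts, an absolute log2 fold change of at least 1. Standard errors were taken as the absolute log2 fold change divided by the square root of F and are approximate. CPM values of named genes were scaled by TMM, unless total counts are named, and are given as mean ± SD over embryos. Late means and SDs over 10 embryos count 10 h replicate 1, where 3 reads correspond to 788 CPM by total counts. A zero in that library is thus no measurement of a low gene. The TMM factor of 10 h replicate 1, from 3808 reads, was 3.7.

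The rule for named genes took the 10 largest rises and falls per window contrast among called genes with a name in the annotation, the 5 largest of each kind for the other results, and 4 members of each gene list. By its part for genes without names, the text gives for each contrast the 2 called genes with the largest rise and the 2 with the largest fall among those with a mean of at least 20 CPM over the 40 embryos. For genes called in opposite directions in the 2 steps, the smaller of the 2 changes set the order, and for intervals the rule was applied to the interval with most calls and to 13 to 20 h. Any other gene ID was chosen after its values were seen, which is said where it appears.

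Similarity between embryos was the Spearman correlation of log2(CPM + 1), scaled by total counts, across the tested genes. The mean over same-age pairs was compared with random pairings by a one-sided permutation test with 100000 resamples. For the number of genes detected, each embryo with at least 100000 gene counts was thinned at random to 264033 counts, the lowest total among them, and window means were compared by exact two-sided permutation tests. These steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. Binomial intervals are at 95% (Wilson for shares, Clopper-Pearson for ratios of 2 counts). A fold against a group with no reads is given as a lower bound against 3 counts over the group.

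The test was tested on simulated data made from the real gene means, library sizes and dispersions, with 9576 genes in the fit. For late minus early, 28% of 100 genes changed 2-fold and 76% of 100 genes changed 4-fold were called, with 5 false calls among 109. For 3 to 4 h, with 1 interval tested alone, 17% of 100 genes changed 4-fold and 74% of 100 genes changed 16-fold were called, with 1 false call among 92. Same-age embryos were checked for a library present more than once. Their counts differed by more than sampling noise at every time, with a chi-square per degree of freedom between 2.76 at 10 h and 91.08 at 2 h.

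Alternatives were DESeq2 1.42.0, median-of-ratios scaling in edgeR, total counts with no composition factor, no filter on low counts, a mean of at least 10 CPM, a replicate block by library pool, a natural spline of time rank with 5 degrees of freedom, a 3-level window factor, other window limits, glmTreat against a log2 fold change of 1, thinning to equal totals (without 10 h replicate 1, which has under 100000 reads), and leaving out each embryo in turn. Fits within 1 pool, which holds 1 embryo per time, used the 3-level window factor, so they differ from the 20-level fit in the model as well as in the number of embryos and are set beside the window factor fit of all 40 embryos. The left-out embryo's age mate was then assumed to vary like the other embryos, and the genes tested were kept.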

Results

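The series followed gene expression through the embryonic development of the ctenophore Mnemiopsis leidyi, a comb jelly. Single embryos were sequenced at 0, 1, 2, 3, 4, 4.5, 5, 5.5, 6, 6.5, 7, 7.5, 8, 8.5, 9, 10, 11, 12, 13 and 20 h, with 2 embryos at each of the 20 times. The 40 embryos held 74710527 reads in gene models. In 36 of them the total lay between 977034 and 4511124 reads, with a median of 1889388.5. The other 4 were shallower, with 580587 reads in 4 h replicate 1, 343202 in 8.5 h replicate 2, 264033 in 5.5 h replicate 2 and 3808 in 10 h replicate 1. A count of 3 reads corresponds to 788 CPM in 10 h replicate 1 and to 11.4 CPM in 5.5 h replicate 2, so genes below those levels were not measurable in these 2 libraries.

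**Figure D1:**
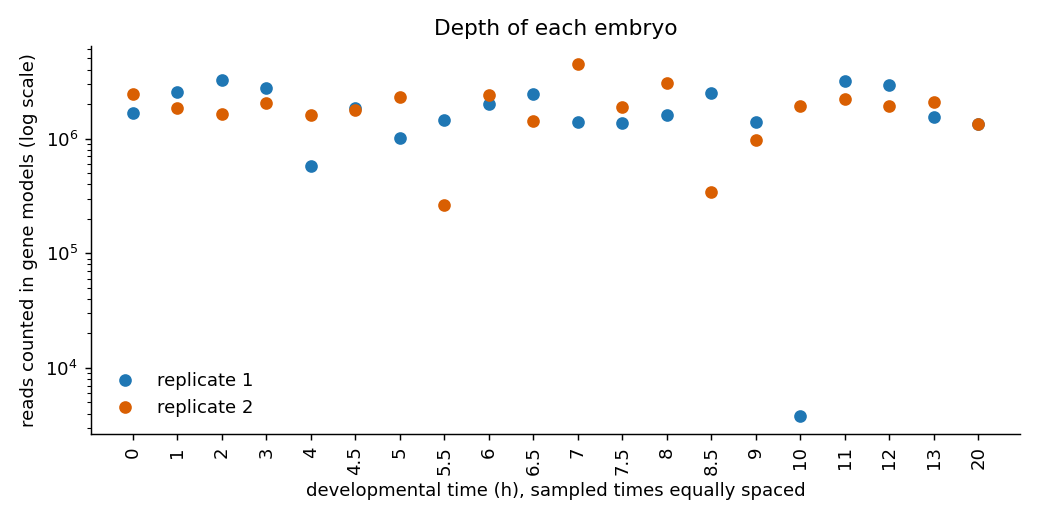
Reads counted in gene models (log scale) in each of the 40 embryos, by developmental time in hours, with replicate 1 in blue and replicate 2 in orange. The library of 10 h replicate 1 holds 3808 reads, and the next shallowest holds 264033.

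Embryos of the same age resembled each other, and the series ran gradually from one end to the other. The mean Spearman correlation of the 20 same-age pairs was 0.8716, against 0.7633 for random pairs (one-sided permutation p = 1e-05, the smallest that 100000 resamples can give). Same-age correlations ranged from 0.751 at 8.5 h to 0.955, apart from 0.385 at 10 h. At 8.5 h 1 library holds 343202 reads, and at 10 h 1 library holds 3808. Without 10 h replicate 1, the nearest embryo was of the same age for 6 of 39 embryos, within 1 sampled time for 31 and within 2 sampled times for 37. The nearest embryo came from the same library pool for 24 of the 39. Embryos of 0 h and 20 h had a median correlation of 0.586. Up to 7.5 h each embryo was closer to the 0 h embryo of the other pool than to its 20 h embryo. At 8 h both embryos were closer to 20 h, with correlations of 0.761 and 0.787 against 0.734 and 0.770 with 0 h. The 8.5 h embryos were split, and from 9 h on every embryo was closer to 20 h. These correlations are across genes, which are not independent replicates.

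**Figure D2:**
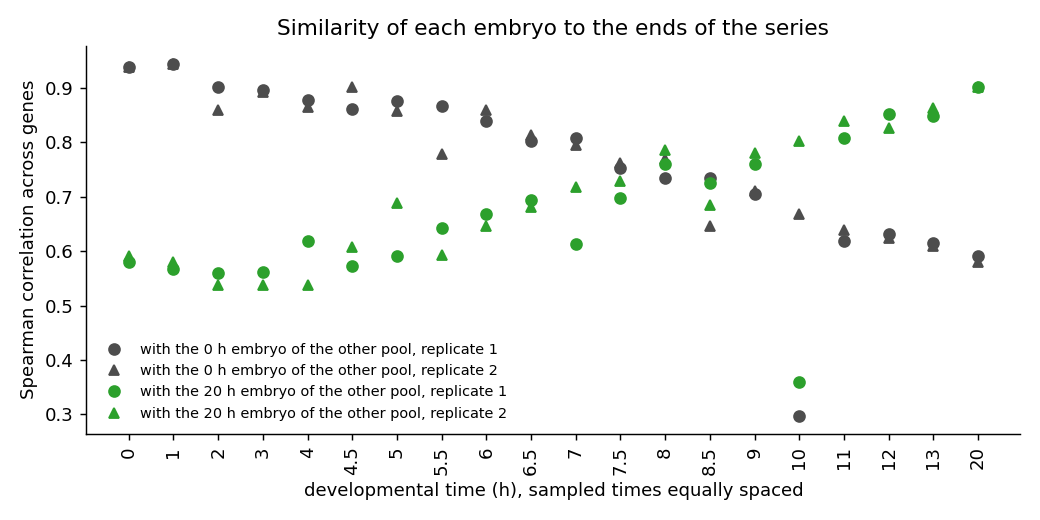
Spearman correlation across genes of each embryo with the 0 h embryo (grey) and the 20 h embryo (green) of the other library pool, by developmental time in hours, with circles for replicate 1 and triangles for replicate 2. The curves cross at about 8 h, and both points of 10 h replicate 1, at 0.297 and 0.359, lie far below the rest.

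More genes were detected in older embryos at equal totals of gene reads, while the number of molecules behind those reads is not known. After thinning to 264033 reads, early embryos had 6412.5 ± 219.9 genes with at least 1 read (SD, n = 8), middle embryos 7311.2 ± 513.0 (SD, n = 22) and late embryos 8485.4 ± 380.6 (SD, n = 9, without 10 h replicate 1). Middle embryos exceeded early ones by 898.7 genes (exact permutation p = 6.42e-05, adjusted over the 3 comparisons 6.42e-05). Late embryos exceeded middle ones by 1174.3 genes (exact permutation p = 8.93e-07, adjusted 2.68e-06) and early ones by 2072.9 (exact permutation p = 4.11e-05, adjusted 6.17e-05). Without thinning the difference between middle and early was 759.6 genes (exact permutation p = 0.0938). With at least 3 reads asked of a gene after thinning, the differences were smaller. They were 444.4 genes for middle minus early, 675.6 for late minus middle and 1119.9 for late minus early (exact permutation p = 0.000665, 1.52e-05 and 4.11e-05).

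**Figure D3:**
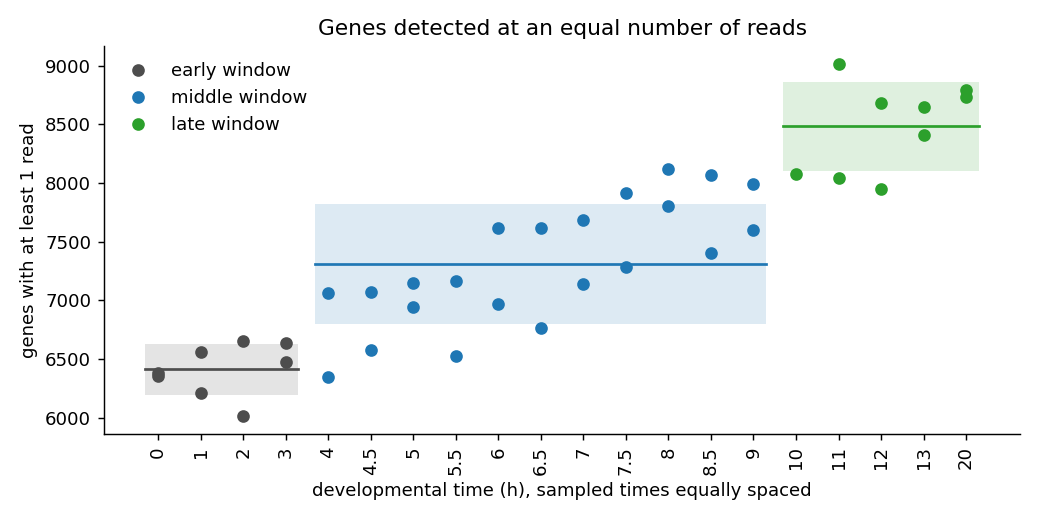
Genes with at least 1 read in each embryo after thinning to 264033 reads, by developmental time in hours; lines are window means and bands 1 SD. The window means are 6412.5, 7311.2 and 8485.4 genes, and 10 h replicate 1 is left out.

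Of 9576 genes tested, 4621 changed over the 20 times (edgeR quasi-likelihood F test, adjusted p below 0.05). Their highest fitted level lay in the late window for 2450 genes (53.0%), in the middle window for 1200 and in the early window for 971, although 11 of the 20 times are in the middle window. The single time with most maxima was 20 h with 936 genes, and the one with most minima was 0 h with 1341 genes. The number of genes changing with time was 2530 with a minimum mean of 10 CPM, and 2667 with libraries thinned to equal totals.

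**Figure D4:**
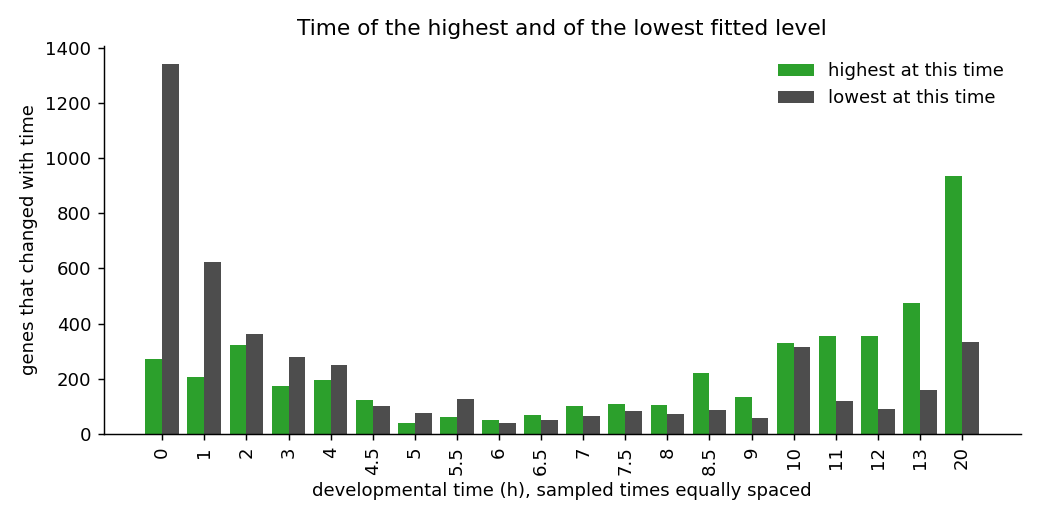
Number of the 4621 genes that changed with time whose fitted level was highest (green) or lowest (grey) at each developmental time in hours. Maxima gather at 20 h (936 genes) and minima at 0 h (1341 genes). The values at 10 h, 329 maxima and 315 minima, include the library of 3808 reads.

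The contrast middle minus early asks which transcripts change between 0 to 3 h and 4 to 9 h. ML034630a rose from 0.248 ± 0.443 CPM in early embryos (SD, n = 8) to 120.2 ± 55.4 in middle embryos (SD, n = 22), and its log2 fold change was 9.30 ± 0.49 (SE). With 4 early reads behind it, this value ran from 7.51 with 4 h counted as early to 16.29 with DESeq2 over the alternatives. ML216327a rose from 0.0792 ± 0.224 to 43.3 ± 24.4 CPM. It had 1 read in all early embryos and 1711 in middle ones, a ratio of 816 with a 95% counting interval of 146 to 32200. ML42442a fell from 110.5 ± 82.0 to 21.3 ± 27.0 CPM, a log2 fold change of -2.83 ± 0.33 (SE), and ML135620a from 1177 ± 669.1 to 192.8 ± 129.7 CPM, a log2 fold change of -2.69 ± 0.19 (SE). The edgeR adjusted p was 1.67e-13, 6.49e-13, 6.03e-08 and 5.55e-12 for the 4 genes in this order. In all, 1860 genes were called, 1330 higher and 530 lower in the middle window. The median absolute log2 fold change was 2.78 among the higher genes and 1.24 among the lower ones, and 379 of the higher genes and 0 of the lower ones exceeded 16-fold by the fitted value. With genes that had no early read set at their lower bound, the median stayed at 2.78 and 376 exceeded 16-fold. The lower genes numbered 247 with a mean of at least 10 CPM, 94 with glmTreat, 265 after thinning, and with the window factor 385 in all embryos, 229 in pool 6 and 221 in pool 12, where the higher genes numbered 961, 886, 694, 2526, 1800 and 1379. Without 5.5 h replicate 1 the split was 877 higher (middle minus early, higher) and 606 lower (middle minus early, lower), and with DESeq2 2068 and 558. The count was 2911 with a 3-level window factor, 980 with glmTreat, 1208 with a mean of at least 10 CPM and 959 after thinning. With the 3-level window factor, 2029 genes were called within pool 6 alone and 1600 within pool 12 alone, against 2911 with that model in all embryos.

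The contrast late minus middle covers the step to 10 to 20 h. ML218939a rose from 14.5 ± 19.5 CPM in middle embryos (SD, n = 22) to 1402 ± 998.9 in late embryos (SD, n = 10), a log2 fold change of 7.72 ± 0.30 (SE), and was highest at 20 h. ML02963a rose from 1.16 ± 2.81 to 253.6 ± 361.8 CPM (log2 fold change 7.60 ± 0.57, SE), also with its maximum at 20 h, where replicate 2 had 1178 CPM. ML25401a fell from 47.6 ± 62.6 to 0.444 ± 0.816 CPM (log2 fold change -6.47 ± 0.74, SE), and ML26355a from 895.3 ± 857.3 to 10.2 ± 5.44 CPM (log2 fold change -5.50 ± 0.40, SE). The edgeR adjusted p was 2.84e-17, 5.41e-11, 8.74e-08 and 2.75e-12 in this order. There were 3278 called genes, 2486 higher and 792 lower in the late window, with median absolute log2 fold changes of 2.47 and 1.33 by the fitted values and of 1.72 and 1.45 by summed reads. Over 16-fold there were 473 higher and 30 lower genes by the fitted values, and 225 and 29 by summed reads. With the 3-level window factor 3072 genes were called in all embryos, 2468 within pool 6 alone and 1909 within pool 12 alone, while with the 20-level factor the count was 1567 with a mean of at least 10 CPM and 1999 with glmTreat. Without 10 h replicate 2, when 10 h rests on the library of 3808 reads, 1151 genes were called, 166 higher and 985 lower, so that the balance between rises and falls was turned around by this library, and ML02963a had an adjusted p of 1 (edgeR) with a log2 fold change of 6.35. Without both 10 h embryos 3559 were called, 2657 higher (late minus middle, higher) and 902 lower (late minus middle, lower). With the window factor the higher genes numbered 2209 in all embryos, 1521 in pool 6 and 1361 in pool 12. With the 20-level factor the split was 1034 higher and 533 lower with a mean of at least 10 CPM. It was 1725 and 274 with glmTreat, and 1574 and 661 after thinning. ML25401a was no longer called without 8.5 h replicate 1 (log2 fold change -6.04) or without 9 h replicate 1 (-6.13), and after thinning ML25401a (-4.52) and ML02963a (5.86) each had an adjusted p of 1 (edgeR).

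The contrast late minus early compares the ends of the series, where the called rises were larger in the median than the falls. ML10112a rose from 0.163 ± 0.356 CPM in early embryos (SD, n = 8) to 272.4 ± 274.4 in late embryos (SD, n = 10), with a log2 fold change of 10.56 ± 1.15 (SE) that rests on 4 early reads and was 9.17 after thinning and 17.14 with DESeq2. ML056510a rose from 0.548 ± 0.509 to 594.2 ± 304.6 CPM (log2 fold change 10.56 ± 0.79, SE, and 14.09 with DESeq2), and both were highest at 13 h. ML104343a fell from 7636 ± 3827 to 82.0 ± 36.7 CPM (log2 fold change -6.72 ± 0.42, SE), and ML04811a from 601.5 ± 116.7 to 3.74 ± 2.08 CPM (log2 fold change -7.22 ± 0.37, SE). The edgeR adjusted p was 1.54e-08, 4.2e-12, 1.65e-13 and 7.58e-15 in this order. In all, 5100 genes were called (53.3% of those tested), 3379 higher (66.3%) and 1721 lower in late embryos. The median absolute log2 fold change was 4.27 among the higher genes and 1.54 among the lower ones. Of the higher genes 326 had no read in any early embryo, and with these at their lower bound the median was 4.17, while by summed reads the medians were 3.80 and 1.71. By the same bound 1779 higher genes exceeded 16-fold, against 25 lower ones, and by summed reads 1578 and 24. The median log2 fold change of all tested genes was 0.38 with TMM, 0.44 with median-of-ratios scaling in edgeR, 0.55 with DESeq2 and 0.15 with total counts, and changes are relative to that scale. With the 3-level window factor 5322 genes were called in all embryos, 4777 within pool 6 alone and 4444 within pool 12 alone, with 3669 called in the same direction in both. Of the 5100 genes, 99.4% had the same sign in both pools. These genes were called from both pools together, so opposite signs were unlikely by that selection. With a mean of at least 10 CPM 2626 genes were called, 1580 higher and 1046 lower, and with glmTreat the split was 2939 and 930. Without 10 h replicate 2 the count was 2016 and the balance turned around, with 274 higher (late minus early, higher) and 1742 lower (late minus early, lower), and ML10112a and ML056510a had adjusted p-values of 1 (edgeR) with log2 fold changes of 8.22 and 8.18. Without both 10 h embryos 5438 genes were called, 3528 higher and 1910 lower.

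Transient middle genes are those called in opposite directions in the steps into and out of the middle window. Among those higher in the middle the rule named ML25401a and ML26355a. ML26355a stood at 10.3 ± 8.85 CPM in early embryos (SD, n = 8), 895.3 ± 857.3 in middle ones (SD, n = 22) and 10.2 ± 5.44 in late ones (SD, n = 10), with a maximum at 7 h. ML25401a stood at 0.553 ± 0.960, 47.6 ± 62.6 and 0.444 ± 0.816 CPM, with a maximum at 5.5 h. The opposite course was shown by ML32311a, at 91.6 ± 70.1, 28.2 ± 19.5 and 60.7 ± 30.2 CPM, and by ML056926a, at 45.2 ± 8.87, 13.4 ± 6.47 and 25.6 ± 10.4 CPM. For the rise of these from middle to late the edgeR adjusted p was 0.00269 and 6.77e-05. In all, 80 genes were higher and 33 lower in the middle window than in both others, fewer than the 110 and 137.6 that independent lists of the same sizes would share. By contrast 695 genes rose in both steps, where independent lists would share 345.3, and 99 fell in both, where they would share 43.8. Both steps use the same middle embryos. With times reassigned at random within pools the log2 fold changes of the 2 steps had a median covariance of -0.202 (range -0.757 to 0.317) and a median correlation of -0.405 (range -0.774 to 0.422), against 1.18 and 0.41 observed. The observed correlation thus lay within the range of the random ones and the covariance above it. The random arrangement with 0.422 followed age in part, with mean ages of 4.81, 7.05 and 9.35 h in its windows. With the first step taken from pool 6 and the second from pool 12 the covariance was 1.22 and the correlation 0.391, and with the pools exchanged 1.19 and 0.37. These correlations are across genes. The number of genes higher or lower in the middle window was 54 with glmTreat, 66 after thinning, and 74 with a mean of at least 10 CPM, and with the 3-level window factor 110 in all embryos, 81 in pool 6 alone and 51 in pool 12 alone. The genes lower in the middle (transient middle genes, lower) numbered 3 with glmTreat, 11 with a mean of at least 10 CPM, 13 after thinning, and with the window factor 25 in all embryos, 14 in pool 6 and 9 in pool 12. They numbered 1 without 10 h replicate 2, 56 without 5.5 h replicate 1, 50 without 8.5 h replicate 1, 20 without 0 h replicate 1 or 3 h replicate 2, 18 without 1 h replicate 1, and 19 without 2 h replicate 1 or 3 h replicate 1. Those higher in the middle (transient middle genes, higher) numbered 47 without 8.5 h replicate 1, 51 with glmTreat, 53 after thinning, and with the window factor 85 in all embryos and 42 in pool 12. Both kinds together were 58 without 10 h replicate 2, when ML32311a and ML056926a changed sign from middle to late (log2 fold changes -0.63 and -0.54 against 1.19 and 1.16). With glmTreat ML32311a was not called in the step into the middle window either (edgeR adjusted p = 0.463 for ML32311a middle minus early). Neither was called in the step out of it with glmTreat or in pool 12 alone, where the log2 fold change of ML32311a late minus middle was 1.12 and that of ML056926a late minus middle 0.95. The latter was also not called after thinning (0.99) or with 9 h counted as late (0.79). ML25401a middle minus early was not called without 8.5 h replicate 1 (6.00), without 9 h replicate 1 (6.09) or after thinning (5.01).

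**Figure D5:**
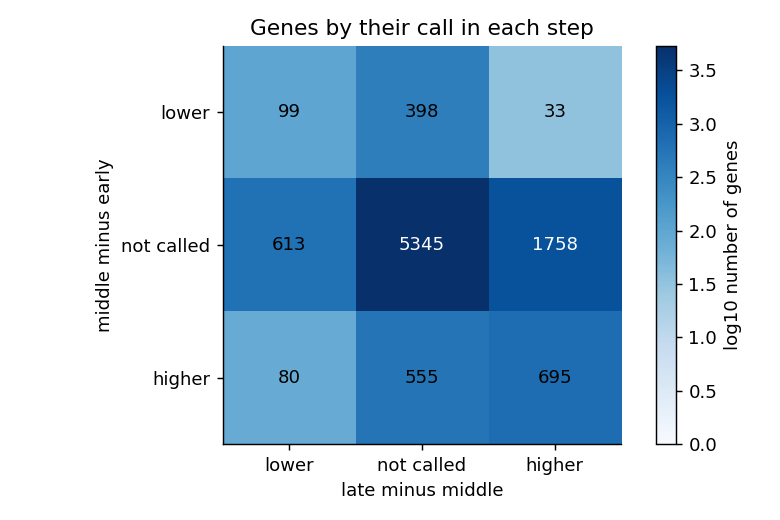
Number of tested genes by their call in the step from early to middle (rows) and in the step from middle to late (columns), with shading on a log10 scale. The largest called class is the 1758 genes called higher from middle to late and not called from early to middle. The smallest is the 33 genes lower in the middle window than in both others.

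Between neighbouring times few genes passed the test, which compares 2 embryos with 2. Of 25 calls over the 19 intervals, 14 fell between 3 and 4 h, all of them rises. In this interval (interval 3 to 4 h) the count was 1 without either 3 h embryo, 8 without 4 h replicate 1, 24 without 4 h replicate 2 and 5 without the 4 shallow libraries, and 58 with DESeq2, 146 without a filter, 7 with glmTreat and 8 after thinning. ML034630a had 0 reads at 3 h and 153 at 4 h, which makes it at least 113-fold higher, with 166.4 and 31.1 CPM in the 4 h embryos (adjusted p = 6.88e-05, edgeR). ML30695a rose from 1.34 and 1.96 CPM to 789.5 and 674.1 CPM (log2 fold change 8.76 ± 1.21, SE, edgeR adjusted p = 0.00231). Its edgeR adjusted p was 0.184 without 3 h replicate 1 and 0.13 without 3 h replicate 2, with log2 fold changes of 8.49 and 9.09. There were 4 calls between 1 and 2 h, 4 between 2 and 3 h and 3 between 13 and 20 h, the longest interval at 7 h. DESeq2 called 39, 18 and 9 genes in these 3 intervals, and glmTreat 1, 1 and 0. The calls were 130, 29 and 82 without a filter on low counts, and 0, 0 and 5 after thinning. They were 5, 7 and 5 with the pool as a block, and 1, 3 and 2 with total counts. The count between 1 and 2 h (interval 1 to 2 h) was 0 without 2 h replicate 2 and 9 without 4 h replicate 2. It was 1 without either embryo of 1, 3, 7.5 or 13 h or without 10 h replicate 1, and 2 without either embryo of 8 or 11 h or without 2 h replicate 1, 5 h replicate 2 or 20 h replicate 2. The count between 2 and 3 h (interval 2 to 3 h) was 0 without replicate 1 and 1 without replicate 2 of either time. Between 13 and 20 h ML14303a rose (log2 fold change 6.50 ± 1.11, SE, edgeR adjusted p = 0.0438), ML270547a rose (3.55 ± 0.62, SE, edgeR adjusted p = 0.0369) and ML141114a fell (-5.82 ± 1.00, SE, edgeR adjusted p = 0.0301), and none of the 3 passed with glmTreat. Each of the 3 also lost its call without either 3 h embryo, without either 13 h embryo or without 20 h replicate 2. The call of ML14303a 13 to 20 h was lost with DESeq2 (log2 fold change 6.57), median-of-ratios scaling (6.58) and total counts (6.49), and without 10 h replicate 1, 12 h replicate 2, either 7.5 h or either 11 h embryo. That of ML141114a was lost without 20 h replicate 1, and that of ML270547a without 1 h replicate 1, after thinning and without the 4 shallow libraries. In the other 15 intervals edgeR called 0 genes, with 177 to 698 at an unadjusted p below 0.05 where chance gives 478.8, and DESeq2 called 0 to 19. The total over consecutive intervals rests on single libraries and on the method. It was 42 (23 between 3 and 4 h) with the pool as a block, 206 with DESeq2, 922 without a filter on low counts, 9 with glmTreat, 15 after thinning and 16 without both 10 h embryos. It was 2 and 3 without 3 h replicates 1 and 2, 14 without either 13 h embryo, 16 without either 7.5 h embryo or without 10 h replicate 1, 40 without 5 h replicate 1, 50 without 8.5 h replicate 1, 51 without 4 h replicate 2 and 58 without 10 h replicate 2.

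The windows were also compared between the library pools. A test of the interaction between window and pool gave 0 genes at an adjusted p below 0.05 (edgeR), and 457 at an unadjusted p below 0.05 where chance gives 478.8; no other tool was run for it. The late minus early log2 fold changes of the pools had a Spearman correlation of 0.907 across genes. The pools themselves differed in level: 1295 genes had an adjusted p below 0.05 between them (edgeR), 437 higher and 858 lower in pool 12, with a median absolute log2 fold change of 0.838.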

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

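Of the tests in this part, the correlation of the pool difference with the late minus early change, the same-age comparisons of the pools, the share of reads outside gene models and the random reassignments were chosen only after the result was seen. In 40 sets of early or late values, 8 held an embryo far from the others of its window. For independent, normally distributed values chance gives about 1 in 20 sets, or 2.0. Low CPM values with many zeros and sets that share a library depart from that, so the chance number for these sets is not known.

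In the late window 3 of the 8 concern 10 h replicate 1, the library with 3808 reads. It had 18.69% of its reads in gene models (27.12% to 33.43% in the other late embryos) and 68.71% not aligned (45.08% to 50.7%). The other is ML056926a, which had 0.0 CPM in that library, where 3 reads correspond to 788 CPM by total counts, and 17.3 to 36.4 CPM in the others. Of its 1093 reads in genes called between late and early embryos, 74.3% fell in the genes higher in late embryos (95% Wilson interval 71.6 to 76.8), against 76.3% in 10 h replicate 2 and 44.3% in the other libraries of pool 6 together.

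In 3 sets low early levels rest on few reads. ML034630a had 1.267 CPM in 2 h replicate 2 and at most 0.413 in the other early embryos, ML216327a had 0.6335 CPM in 2 h replicate 2 from its 1 early read, and ML10112a had 1.005 CPM in 3 h replicate 1 and at most 0.301 elsewhere in the window. In the late window ML216327a had 25.13 CPM in 10 h replicate 2 and at most 10.8 in the others, and ML02963a had 1178 CPM in 20 h replicate 2 and at most 490.8 in the others.

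Reads outside gene models, which no comparison used, made up a median of 32.95% of aligned reads. Their share was lower in pool 12 than in pool 6 by 5.19 percentage points on average (-5.19 ± 4.21, SD, 17 of 19 same-age pairs, permutation p = 4e-05, adjusted over 4 measures 0.00012), and the ambiguous share was higher by 0.79 ± 0.58 points (18 of 19 pairs, permutation p = 6e-05, adjusted 0.00012).

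The 1295 genes that differ between the pools are the first pattern weighed. Embryos of 1 pool being further developed at all times are argued against as the whole cause. The Spearman correlation, over these genes, between the pool and the late minus early log2 fold changes was -0.104. The pool change is 1 value for all times, so a lead that changed sign with time could cancel in it and is not excluded. As a part of the cause, further development of 1 pool stays open. At equal totals pool 6 had 402.6 ± 391.7 more genes detected (SD, 16 of 19 same-age pairs, permutation p = 0.00067, adjusted over 2 measures 0.0013). The share of late-higher genes in its reads from late-higher and late-lower genes exceeded that of pool 12 by 0.54 ± 5.74 points (SD, 12 of 19 pairs, permutation p = 0.69, adjusted 0.69). Offsets of opposite sign cancel in this mean. Pool 6 had the higher share at every time from 0 to 4.5 h, and a much lower one at 5 h (19.6% against 33.4%) and 7 h (38.5% against 51.3%). The 4 shallow libraries do not account for the pool difference either, since 1431 genes differed without them, 1170 of them among the 1295 and all with the same sign. A different place of the reads relative to the gene models may contribute, given the -5.19 points above. It cannot be told apart from the embryos' origin, because each pool is also 1 set of replicates. Apart from further development of 1 pool, no biological explanation was tested, since no group of the design separates the pools.

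The second pattern is the larger number of genes detected in late embryos. The comparison was made at equal totals, and the early libraries were the deeper ones, with a mean of 2268000 reads against 1850000 over all 10 late ones. That late mean includes the 3808 reads of 10 h replicate 1, which the comparison left out, so the gap between the libraries compared was smaller. A few genes taking more of the early reads are argued against by 2079.9 more genes in late embryos (8209.0 ± 255.1, SD, n = 9, against 6129.1 ± 134.5, SD, n = 8) when each library's 100 most abundant genes were left out and the rest thinned to 132951 reads (exact permutation p = 4.11e-05). The 10 most abundant genes took 11.1% ± 1.83 of early and 11.4% ± 1.84 of late reads. That more genes are in use in later embryos remains as a hypothesis, tested on the same embryos, and the total RNA per embryo was not measured.

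Chance in the assignment of times was examined with 29 random reassignments within the pools, each of which kept 1 embryo of each pool at every time. Of the 30 arrangements, the real one included, only 1, the real one, gave as many genes in each of the 5 results. Times unrelated to expression can thus be excluded at that resolution, but the window counts are not tested separately by this. Reassigned pairs mixed ages, which widens the spread within a time and can lower the number of calls. An arrangement with mean ages of 4.19 h in the early and 8.85 h in the late window still gave 0 late minus early calls. The real counts and the highest of the others were 4621 and 14 for genes that changed with time, 1860 and 1500 for middle minus early, 3278 and 0 for late minus middle, 5100 and 0 for late minus early, and 113 and 0 for genes higher or lower in the middle window. The arrangement with 1500 genes had put embryos with a mean age of 10.69 h in the early window and of 5.86 h in the middle window. Another, with mean ages of 10.44 h and 5.7 h, gave 0 middle minus early calls. In the arrangement with 1500 genes the shallowest library was placed at 10 h, in the late window. In the arrangement with mean ages of 10.44 h and 5.7 h it was placed at 1 h, in the early window. These arrangements thus cannot separate mean age from the place of that library, and the cause of the 1500 genes was not tested.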

How the results depend on the processing

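Thinning for results other than the intervals, the fits without 4 libraries or without both 10 h embryos, and the fits within 1 pool were added after the data were seen. Spike-in scaling and the gene list tests were not run. Same-age similarity (0.8439 to 0.9183) and genes detected, late minus early (1119.9 to 2455.0), stayed past their thresholds in every alternative run, while genes detected, middle minus early, did not without thinning (759.6). With a mean of at least 10 CPM, which tests fewer genes, the counts were 2530 for genes changing with time, 1208 for middle minus early, 1567 for late minus middle, 2626 for late minus early and 74 for transient middle genes. After thinning, which removes reads and leaves out 10 h replicate 1, they were 2667, 959 and 66 for time, middle minus early and the middle genes, and 15 for the intervals, where leaving out that library alone gave 16. With glmTreat, a stricter test, they were 980 for middle minus early, 1999 for late minus middle, 54 for the middle genes and 9 for the intervals. Pool 12 alone, with fewer samples and a 3-level window factor, gave 1909 for late minus middle and 51 for the middle genes, against 3072 and 110 with that factor in all embryos. Middle minus early gave 2911 with a 3-level window factor, and the consecutive intervals 206 with DESeq2, 922 without a filter and 16 without both 10 h embryos; the cause was not tested. The replicate block by pool gave 42 calls over the intervals (23 at 3 to 4 h against 14) and changed no call count of the other results by over 1.5 times. Leaving out 1 embryo gave 4299 to 4999 over time, 1483 to 2049 for middle minus early, 1151 to 3359 for late minus middle, 2016 to 5185 for late minus early, 58 to 127 for the middle genes, 2 to 58 for the intervals, 0.8672 to 0.8972 for same-age similarity. The low ends 1151, 2016 and 58 come from leaving out 10 h replicate 2, where ML32311a (-0.63) and ML056926a (-0.54) reversed from middle to late (highest without another embryo 1.95 and 1.26); only the library of 3808 reads then stands for 10 h, and the higher genes fall to 166 for late minus middle and 274 for late minus early. Of the values of named genes under alternatives 1201 stayed past the threshold with the same sign, 50 no longer passed and 2 reversed. Depth limits 10 h replicate 1, where 3 reads correspond to 788 CPM. In simulated data 17% of 4-fold changes between 3 and 4 h were called, which does not separate depth from the number of embryos.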

Other observations

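The tests of neighbouring genes were set before their results were seen. The descriptions of genes first seen in later embryos and of abundant genes were chosen after values were seen.

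A set of 338 genes was nearly absent from early embryos and present in late ones. Of these, 309 were called higher in late minus early, which the choice of the set on the same embryos largely implies. The 338 genes had at most 3 reads over all 8 early embryos, out of 18142700 reads, and at least 10 CPM over the late embryos, by summed reads. Their late median was 19.0 CPM and the highest 190.4. The choice itself keeps them below 10 CPM up to 3 h. After that these genes did not appear at once. By 5 h 30 of them had reached 10 CPM, by 7 h 81, by 9 h 190 (56.2%) and by 11 h 294 (87.0%), with 71 first appearances at 11 h, after a step of 1 h, and 39 at 9 h, after a step of 0.5 h. At 10 h nearly all reads come from 1 library. Only 4 genes met the mirror criterion of at most 3 late reads and at least 10 CPM in early embryos. Of 3902 genes with at least 20 CPM at 0 h, 1383 (35.4%) were lower in late than in early embryos and 246 were higher. The other 2273, most of these genes, were not called. A call also asks for an absolute log2 fold change of at least 1, and in simulated data 28% of 2-fold changes were called in this contrast. A gene not called can thus still have changed.

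The most abundant gene model, ML305521a, named after its values were seen, took 2.69% of all gene reads and varied widely between embryos of the same age. Scaled by total counts, its level ran from 352.6 to 74480 CPM over the embryos with at least 100000 reads. The 2 embryos of a time differed by a median of 3.95-fold over 19 pairs, by over 2-fold in 11 of them and by 194-fold at 8.5 h, and its adjusted p over time was 0.995 (edgeR). ML014110a, also named after its values were seen, was among the 15 most abundant gene models. By total counts it fell from 16420 ± 6328 CPM in early embryos (SD, n = 8) to 2342 ± 742.2 in late ones (SD, n = 10). In the fit with TMM scaling its log2 fold change from early to late was -2.54 (edgeR adjusted p = 9.95e-08).

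The third pattern weighed concerns gene order. The IDs hold a 4-digit stem and a running number, and within 1730 of 1747 stems the numbers run from 1 without a gap, so consecutive numbers were taken as neighbours; the sources used here do not state this, and coordinates were not used. Over 5455 pairs of tested genes 1 number apart, the median correlation of time profiles was 0.175, an excess of 0.148 over the mean of 1000 shuffles (permutation p = 0.001, the smallest they can give), consistent with neighbouring genes being used at the same times. One transcript counted in 2 adjacent gene models is argued against as the whole cause by an excess of 0.057 at 2 to 5 numbers apart (17612 pairs, above every shuffle), and the excess was 0.014 at 6 to 10 and -0.006 at 11 to 20. Reads shared between neighbouring models would also make same-age differences correlate, and their excess at 1 number apart was 0.026, too small for the bound set for that cause and too large for the bound against it, so this stays open, as do neighbouring copies of 1 gene, which were not tested. Genes are not independent replicates, and the p covers only the shuffling of genes.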
